A study of Saccharomyces cerevisiae with 4 samples.

How the data were processed

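RNA was measured in 4 libraries of budding yeast of the W-303 background, 2 from a wild-type strain and 2 from a strain whose chromosome III lacks its tRNA genes. Per the labels, cultures in rich medium (YPD) were harvested in early log phase and frozen, total RNA was extracted with a silica column kit, and directional libraries were made and sequenced by a commercial service. The labels call the 2 libraries of each strain biological replicates.

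Each library has a table with an estimated count and a TPM value per reading frame, written by kallisto, which the submitters' processing notes name together with sleuth and the build sacCer3. The kallisto version, its index, its strand setting and its bootstraps are not given in the sources used here. The deposited estimated counts need not be whole, since kallisto divides reads between similar sequences, and 17.4% of them were not whole in wild-type replicate 1. The deposited TPM values divide those counts by length and by the library's total. The tables list 6706 reading frames, and 100% of their lengths are multiples of 3, so these are coding lengths without untranslated regions. RNA that does not come from a listed reading frame, such as tRNA, is not analysed here. The files hold no coordinates. Names and positions were taken from the R64 reference assembly and its annotation, in which 6022 of the systematic names were found, 99.5% of them with the same coding length. The other 684 are named by systematic name and have no position here. The reference is not W-303, so transposon insertions and marker loci can differ from it.

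Estimated counts were rounded to whole numbers. Reading frames with too few counts were removed with edgeR's filterByExpr at its default minimum of 10 counts, leaving 6205. Libraries were scaled by TMM. Groups were compared with edgeR's quasi-likelihood test (edgeR 4.0.16 in R 4.3.3), and p-values were adjusted by the Benjamini-Hochberg method over all reading frames tested. A reading frame was called at an adjusted p under 0.05. Standard errors were computed as the absolute log2 fold change divided by the square root of the F statistic. Levels are counts scaled by library size (CPM), as mean ± SD with n = 2 per strain. With 2 libraries per strain, a permutation of the libraries could not reach the threshold, so every p-value of a gene comes from the fitted model.

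Gene lists were tested with camera (limma 3.58.1) at the preset correlation of 0.01, with Benjamini-Hochberg adjustment over 51 lists that were written before the data were examined. Camera with an estimated correlation and fry were run beside it. The chromosomes were tested in the same way as 16 sets. The share of called genes on chromosome III was compared with that of the other nuclear chromosomes by a two-sided Fisher's exact test, leaving out the 6 marker and auxotrophy genes. Genes within 1 kb of an annotated tRNA gene of chromosome III were compared with 10000 random lists of chromosome III genes of the same size, drawn within 5 bins of mean expression, by the difference in median absolute log2 fold change in a one-sided permutation test, with the markers left out here too. LEU2, which lies within that distance, is therefore in neither group. The 95% intervals of these differences are from 2000 bootstrap draws. The same test was run on the other chromosomes, where the tRNA genes are intact.

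Genes were named by a rule written before the data were examined. It takes the 12 largest rises and the 12 largest falls among called genes whose libraries did not overlap between strains and whose mean log2 CPM was at least 3. It adds up to 15 called chromosome III genes, all marker genes, all genes of the mating-type loci with the 3 nearest genes on each side of HML and HMR, called genes beside a chromosome III tRNA gene, and up to 4 members of each list described. Other genes named were chosen after their values were seen, and the text says so.

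Depth was 12.48 M and 19.76 M estimated counts in the wild-type libraries and 12.94 M and 14.46 M in the tDNA-less libraries. The biological coefficient of variation was 9.8%. The 2 libraries of a strain differed by far more than counting noise, with a chi-square per degree of freedom of 62.6 in wild type and 46.1 in the tDNA-less strain, so they were treated as separate libraries. The test was checked on simulated counts with the same means, depths and spread, with 6170 genes tested, in which 200 genes were changed and another 30, those of a single list, were shifted by 0.4 on the log2 scale. It recovered 64.2% of 1.5-fold changes, 88.1% of 2-fold changes and 95.5% of 4-fold changes, and of its 189 calls 13 were genes of the shifted list and 11 were genes that had not been changed.

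Alternatives tried were DESeq2's size factors, no filter on low counts and a minimum mean of 50 counts, DESeq2 1.42.0, limma-voom, limma-trend on log2(TPM + 1), the replicate number as a block, each library left out in turn, an offset for GC content and other distances from the tRNA genes. Alternatives chosen after seeing the data, when a first fit had shown the called genes, left out the 4 reading frames with the most counts, the 89 Ty retrotransposon reading frames, or these and YCL021W-A. Outliers within a group were not tested, since each strain has 2 libraries.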

Results

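The series compared the transcriptome of wild-type budding yeast with that of a strain whose chromosome III carries no tRNA genes. A tRNA gene (tDNA) is transcribed by RNA polymerase III, and the one beside the silent mating-type locus HMR is known as a barrier to the spread of silencing. The comparison asks how expression on chromosome III and elsewhere differs when these genes are gone. The reference annotation places 10 tRNA genes on chromosome III, among 275 in the nuclear genome, and the genotype label of the tDNA-less strain lists 9 numbered deletions without saying which gene each number is. The same label gives LEU2 as a replacement at a pair of these sites and HIS3 as a further insertion, while the wild type carries mutant leu2 and his3 alleles. Each strain was measured in 2 libraries. Estimated counts summed to between 12.48 M and 19.76 M per library, and the libraries of each strain are biological replicates per the labels. The reading frames YSH1, ATG7, LTO1 and MSK1 took 39.56% and 30.63% of the counts in wild-type replicates 1 and 2, and 45.09% and 36.07% in tDNA-less replicates 1 and 2. Other reading frames shared 7.54 M, 13.71 M, 7.11 M and 9.25 M counts in that order of libraries.

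The markers separated the strains. HIS3, an enzyme of histidine synthesis on chromosome XV in the reference (721946 to 722608), rose 42.5-fold in the tDNA-less strain, from 10.45 ± 2.76 to 432.5 ± 41.1 CPM (SD, n = 2), a log2 fold change of 5.41 ± 0.16 (SE; edgeR's quasi-likelihood test, adjusted p = 1.5e-07). LEU2, an enzyme of leucine synthesis on chromosome III (91324 to 92418), fell from 123 ± 17.8 to 56.9 ± 3.66 CPM, a log2 fold change of -1.12 ± 0.11 (edgeR, adjusted p = 0.000915). Without tDNA-less replicate 2 the LEU2 call was lost (edgeR, adjusted p = 0.0556). The counts do not tell a mutant allele from an intact one. The remaining auxotrophy genes did not pass the test, with log2 fold changes of -0.28 for CAN1, -0.42 for TRP1, -0.19 for URA3 and 0.06 for ADE2. As a list, the 6 marker genes had a median log2 fold change of -0.236, a mean of 0.577 and a camera test in the upward direction (adjusted p = 0.00168), and the adjusted p with an estimated correlation was 0.603. Over 14 settings its camera adjusted p ranged from 3.45e-05 to 0.849 (on the log2(TPM + 1) scale), passing in 11 and keeping its direction in 12.

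Across the genome, few genes were called as different between the strains. Outside Ty elements and among genes with a mean log2 CPM of at least 3, the largest falls were those of LEU1, OAC1 and BAT1, which act in leucine and branched-chain amino acid synthesis. LEU1, the isopropylmalate isomerase of leucine synthesis, fell 7.56-fold, from 935.3 ± 130 to 123.7 ± 2.93 CPM. OAC1, a mitochondrial carrier of oxaloacetate and isopropylmalate, fell 4.29-fold, and BAT1, the mitochondrial branched-chain aminotransferase, fell 3.75-fold. Under the same limits the largest rises after HIS3 were those of CIT2, the peroxisomal citrate synthase, by 2.66-fold, and YRO2 by 2.24-fold. They were followed by TDH1, a glyceraldehyde-3-phosphate dehydrogenase, by 2.18-fold and MRM1, a methyltransferase of mitochondrial ribosomal RNA, by 2.16-fold. MRM1 lies beside HIS3, the inserted marker, on chromosome XV of the reference. Larger called changes were fitted below that level of expression for YCL021W-A, YFR009W-A and YDL086C-A, which were lower, and for YOR203W and YCR064C, which were higher. YFR009W-A, YDL086C-A and YOR203W were named after their values were seen.

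Of 6205 reading frames tested, 93 were called, 50 higher and 43 lower in the tDNA-less strain (edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). Of these, 28 changed by at least 2-fold, 15 up and 13 down. The median absolute log2 fold change of the called reading frames was 0.78. Ty retrotransposon reading frames made up 13 of the calls, 10 higher and 3 lower, and the other 80 split evenly into 40 higher and 40 lower. Further genes among the largest rises were ADR1, an activator of glucose-repressed genes (log2 fold change 1.05 ± 0.21), and ECM13 (1.02 ± 0.15). Further large falls were those of SAT4, a protein kinase of salt tolerance (-1.61 ± 0.10), ISU2, a scaffold for iron-sulfur clusters (-1.19 ± 0.18), DIC1, the mitochondrial dicarboxylate carrier (-1.15 ± 0.14), and YLL067C, a subtelomeric reading frame (-0.99 ± 0.18). Without tDNA-less replicate 1 the count was 21, of which 19 were among the 93, and without tDNA-less replicate 2 it was 30, of which 23 were. On the scale of log2(TPM + 1), limma called 17 higher and 35 lower, a share of 32.7% higher against 53.8%, with the median of all genes at -0.11. The TPM values were not scaled further between libraries, so this offset makes rises smaller and falls larger there. Loss of the call of a rise on that scale can partly reflect the offset. Other settings raised the count, to 282 with the replicate number as a block and to 211 with an offset for GC content.

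Among the called genes that are named, 53 in number, 14 passed in all 13 refits of the libraries in which they were tested, with LEU1, OAC1, BAT1, SAT4, CIT2, MRM1, MET3 and MET5 among them. TDH1 and ECM13 lost the call when either tDNA-less library was left out (highest adjusted p 0.113 and 0.208). ADR1, YRO2 and YLL067C lost it then too and on the log2(TPM + 1) scale (0.387, 0.331 and 0.291), ADR1 also without wild-type replicate 2, YRO2 also without wild-type replicate 1 and YLL067C without either of those. ISU2 and DIC1 lost it without tDNA-less replicate 1 (edgeR, adjusted p = 0.121 and 0.0575).

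**Figure D1:**
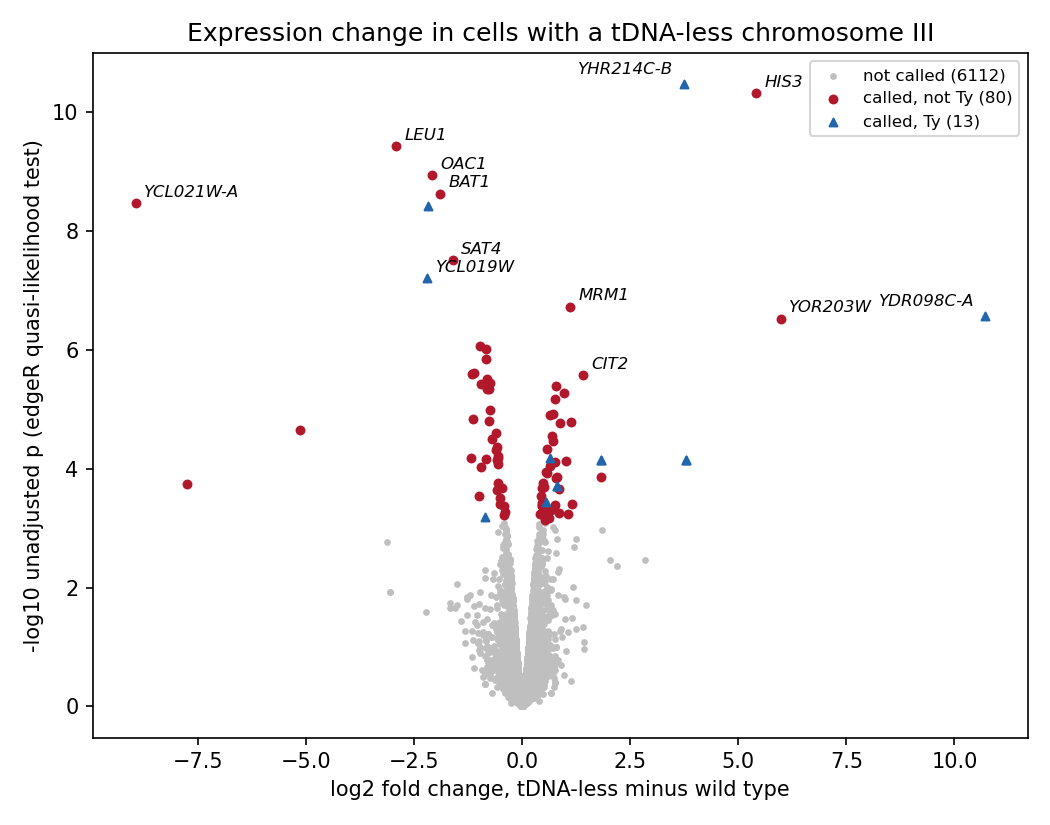
Each point is a reading frame, with the log2 fold change (tDNA-less minus wild type) on the x axis and minus log10 of the unadjusted p on the y axis. Red circles are called reading frames (80), blue triangles are called Ty reading frames (13) and grey points were not called, with HIS3 at 5.41 and LEU1 at -2.92.

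In the amino acid lists the called genes were lower, and many members did not pass. In the list of branched-chain amino acid genes without LEU2, 7 of 13 members fell, 0 rose and 6 did not pass, and 9 fell when adjusted over the list alone. The median log2 fold change was -0.56 (camera, adjusted p = 1.11e-48), and the adjusted p was 0.435 with an estimated correlation. ILV3, a dehydratase shared by the isoleucine, valine and leucine pathways, fell by 0.84 on the log2 scale, with an SE of 0.07. In the sulfur amino acid list, 6 of 21 members fell, 0 rose and 15 did not pass, and 10 fell when adjusted over the list alone (median -0.52, camera adjusted p = 2.89e-14). The adjusted p was 0.603 with an estimated correlation. MET3, the ATP sulfurylase that starts sulfate assimilation, had a log2 fold change of -1.17 ± 0.12, and MET5, a subunit of sulfite reductase, one of -0.98 ± 0.09. MET6, the methionine synthase, fell 1.71-fold and MET17 1.49-fold, and both lost the call when either tDNA-less library was left out (highest adjusted p 0.117 and 0.25), MET17 also on the log2(TPM + 1) scale.

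**Figure D2:**
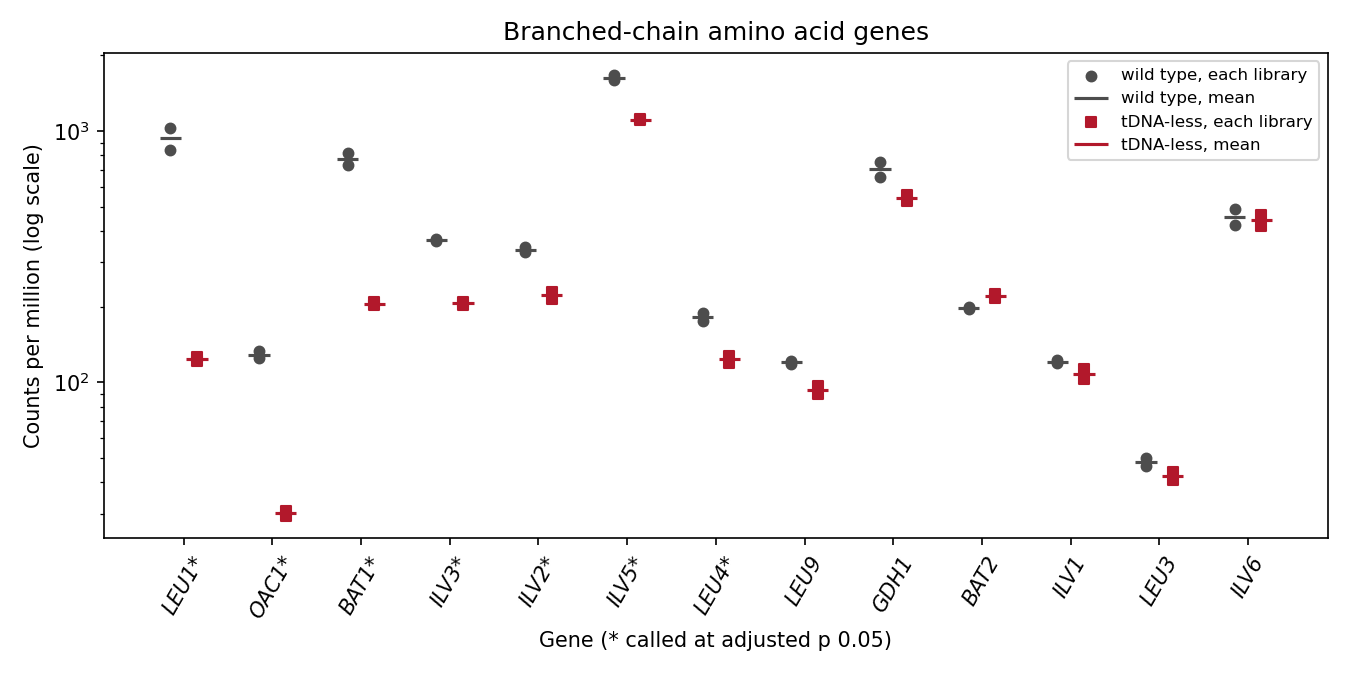
CPM on a log axis for the 13 genes of the branched-chain amino acid list, with each library as a point and the mean of 2 libraries as a line. Grey circles are wild type and red squares are tDNA-less libraries, and an asterisk marks the 7 genes called, among them LEU1 with means of 935.3 and 123.7 CPM.

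Other amino acid lists had smaller medians. The 6 histidine genes without HIS3 did not pass as a list (median -0.106, camera adjusted p = 0.341), with 0 called by edgeR, DESeq2 or limma-voom and 0 at an unadjusted p under 0.05. The list of amino acid and nitrogen permeases held 3 falls among 16 members, 4 when adjusted over the list alone, with BAP2, a branched-chain amino acid permease, down 1.67-fold, GAP1, the general permease, down 1.72-fold and MEP2, an ammonium permease, down 1.5-fold. All 3 calls were lost when either tDNA-less library was left out (highest adjusted p 0.0683, 0.157 and 0.181), and that of MEP2 also on the log2(TPM + 1) scale. Its camera adjusted p was 0.0312, with an adjusted p of 0.677 with an estimated correlation, and over 14 settings the camera value ranged from 0.00848 to 0.245 (without wild-type replicate 2), passing in 10. None of the 16 arginine and lysine genes was called by edgeR, DESeq2 or limma-voom, 4 had an unadjusted p under 0.05 and 3 fell when adjusted over the list alone. Their median was -0.155 (camera, adjusted p = 0.00247, and adjusted p = 0.728 with an estimated correlation). Of 20 aromatic, threonine and serine genes, 1 fell, SER3 (1.34-fold, edgeR adjusted p = 0.042, a call lost on the log2(TPM + 1) scale and when any of the 4 libraries was left out), and 3 fell when adjusted over the list alone. That list had a median of -0.11 (camera, adjusted p = 0.00292, and adjusted p = 0.736 with an estimated correlation). Of 15 purine genes, 0 were called by edgeR, DESeq2 or limma-voom and 0 when adjusted over the list alone, while 6 had an unadjusted p under 0.05 (median -0.205, camera adjusted p = 0.00108, and adjusted p = 0.668 with an estimated correlation). The arginine and lysine, aromatic and purine lists passed in 13 of 14 settings each, and not without wild-type replicate 2 (camera adjusted p from 2.31e-05, 1.06e-05 and 3.19e-05 to 0.245, 0.408 and 0.0564).

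Some genes of mitochondrial respiration rose, while most members of these lists did not pass. In the list of nuclear genes for the respiratory chain and ATP synthase, 5 of 32 members rose, 0 fell and 27 did not pass, and 20 rose when adjusted over the list alone. The median log2 fold change was 0.24 (camera, adjusted p = 8.03e-13), and the adjusted p was 0.603 with an estimated correlation. CYT1, cytochrome c1, rose 1.48-fold, NDI1, the internal NADH dehydrogenase, 1.56-fold, QCR6 1.4-fold and CYC1, cytochrome c, 1.36-fold. In the list of the TCA and glyoxylate cycles, 5 of 21 members rose, 0 fell and 16 did not pass, and 13 rose when adjusted over the list alone (median 0.30, camera adjusted p = 2.38e-11, and adjusted p = 0.603 with an estimated correlation). CIT2 rose from 27.33 ± 5.4 to 73.28 ± 9.03 CPM, ACO1, aconitase, 1.6-fold, and IDH1 and IDH2, the subunits of NAD-dependent isocitrate dehydrogenase, 1.65-fold and 1.69-fold. These 4 genes are also the 4 that rose among 10 members of the retrograde response list, where 6 rose when adjusted over the list alone (median 0.51, camera adjusted p = 1.03e-09, and adjusted p = 0.549 with an estimated correlation). CYT1, NDI1, QCR6, CYC1, ACO1, IDH1 and IDH2 lost the call when either tDNA-less library was left out and on the log2(TPM + 1) scale, with a highest adjusted p from 0.246 for IDH1 to 0.501 for CYC1. NDI1 and CYC1 lost it also without wild-type replicate 1, and QCR6 without wild-type replicate 2.

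Of 67 mitochondrial ribosomal protein genes, 1 rose, MRPL24 (1.55-fold, edgeR adjusted p = 0.0465), the same number as adjusted over the list alone, and 64 had a positive fold change (median 0.19, camera adjusted p = 1.31e-08, and adjusted p = 0.603 with an estimated correlation). MRPL24 kept the call in 6 of 13 refits, with 0 of the 4 that left out a library, and lost it also with the stricter filter, in DESeq2 and on the log2(TPM + 1) scale. Of 5 mitochondrially encoded genes tested, 0 were called by edgeR, DESeq2 or limma-voom, 0 when adjusted over the list alone, and 2 had an unadjusted p under 0.05. Their camera adjusted p was 0.04998, it was 0.736 with an estimated correlation, and over 14 settings the camera value ranged from 8.51e-05 to 0.715 (without wild-type replicate 2), passing in 10.

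Of the ribosome biogenesis genes, all 52 had a negative fold change, and 1 fell, DBP2, an RNA helicase (1.47-fold, edgeR adjusted p = 0.00957), while 10 fell when adjusted over the list alone. The median was -0.16 (camera, adjusted p = 6.65e-09), and the adjusted p was 0.435 with an estimated correlation. DBP2 lost the call when either tDNA-less library was left out and on the log2(TPM + 1) scale (highest adjusted p 0.36). Of 46 tRNA processing and modification genes, 1 fell, TRM11, a tRNA methyltransferase subunit (1.35-fold, edgeR adjusted p = 0.0318), and 4 fell when adjusted over the list alone (median -0.12, camera adjusted p = 0.000989, and adjusted p = 0.674 with an estimated correlation). TRM11 kept the call in 8 of 13 refits and lost it on the log2(TPM + 1) scale and when any of the 4 libraries was left out (highest adjusted p 0.396). In the phosphate regulon, 4 of 17 members fell, both over all genes and when adjusted over the list alone. PHO89, a phosphate transporter, fell 1.76-fold, PHO5 and PHO11, secreted acid phosphatases, 1.62-fold and 1.52-fold, and SPL2 1.42-fold (median -0.17, camera adjusted p = 1.31e-07, and adjusted p = 0.603 with an estimated correlation). Each of these 4 calls was lost without tDNA-less replicate 2 (highest adjusted p 0.0582, 0.213, 0.213 and 0.457), all but that of PHO89 also without tDNA-less replicate 1, and that of SPL2 also without wild-type replicate 2. Those of PHO11 and SPL2 were lost on the log2(TPM + 1) scale as well. PHO5 and PHO11 share 19.8% and 92.58% of their 31-base words with other reading frames, between which shared reads are divided.

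A few chaperone, glycolysis and stress genes rose. Of 17 heat shock chaperones, 2 rose, HSP82 (1.68-fold) and SSA1 (1.63-fold), and 5 rose when adjusted over the list alone (median 0.21, camera adjusted p = 7.44e-07, and adjusted p = 0.603 with an estimated correlation). They share 15.48% and 63.56% of their 31-base words with other reading frames, and both calls were lost when either tDNA-less library was left out and on the log2(TPM + 1) scale (highest adjusted p 0.192 and 0.22), as was that of ENO1 (0.423). Of 17 glycolysis and fermentation genes, 2 rose, TDH1 and ENO1 (1.45-fold), and 3 rose when adjusted over the list alone (median 0.13, camera adjusted p = 0.000744, and adjusted p = 0.677 with an estimated correlation). On the log2(TPM + 1) scale the median of this list was -0.007, and 0.107 relative to the median of all genes. Of 25 cell wall genes, 1 rose, SRL1 (1.38-fold, a call kept in 1 of the 4 refits that left out a library and lost on the log2(TPM + 1) scale), and 4 rose when adjusted over the list alone (camera adjusted p = 0.00116, and adjusted p = 0.674 with an estimated correlation). Of 35 general stress genes, 1 rose, YGP1 (1.71-fold, a call lost without tDNA-less replicate 1 and on the log2(TPM + 1) scale, highest adjusted p 0.123), and 4 rose when adjusted over the list alone (camera adjusted p = 0.00127, and adjusted p = 0.674 with an estimated correlation). Of 14 oxidative stress genes, 0 were called by edgeR, DESeq2 or limma-voom, 4 had an unadjusted p under 0.05 and 2 rose when adjusted over the list alone (camera adjusted p = 0.0122, and adjusted p = 0.674 with an estimated correlation). Without wild-type replicate 1 the glycolysis, cell wall, general stress and oxidative stress lists did not pass (camera adjusted p over the settings from 3.09e-06, 2.95e-05, 8.85e-05 and 0.00192 to 0.0625, 0.152, 0.106 and 0.135).

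In all, camera called 20 of the 51 lists, 11 upward and 9 downward. With an estimated correlation 0 lists passed, with 3 at an unadjusted p under 0.05, and fry called 0, with 13 at an unadjusted p under 0.05. Fry's mixed test, which asks for change in either direction, passed 12. By camera, the lists of RNA polymerase III, silencing factors, condensin and cohesin, histones and mating-type genes did not pass. That of RNA polymerase III passed fry's mixed test (adjusted p = 0.0252), but not fry's test of a single direction (adjusted p = 0.075). The list of RNA polymerase III and its factors had a median of -0.12 (camera, adjusted p = 0.0691), with 0 of 23 members called by edgeR, DESeq2 or limma-voom and 5 at an unadjusted p under 0.05. Silencing factors stood at a median of 0.01 (camera, adjusted p = 0.647), condensin and cohesin at 0.10 (0.178) and histones at 0.17 (0.0574). In each of these 3 lists 0 genes were called by edgeR, DESeq2 or limma-voom, and 4, 3 and 4 had an unadjusted p under 0.05. The 7 a-specific genes had a median of -0.03 with a mean of 0.02 (adjusted p = 0.837), and the 3 alpha-specific genes tested had a median of -0.02 (0.837). The medians of silencing factors and of condensin and cohesin were below 0 on the log2(TPM + 1) scale, and above 0 there relative to the median of all genes.

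On chromosome III, a larger share of genes was called than elsewhere, and calls clustered at tRNA gene sites. With the markers left out, 7 of 162 tested reading frames were called there, 4.32%, against 84 of 6028 on the other nuclear chromosomes, 1.39%, an odds ratio of 3.19 (95% interval 1.23 to 7.03, two-sided Fisher's exact test, p = 0.00949). The odds ratio was 13.55 without tDNA-less replicate 1 and 10.05 without tDNA-less replicate 2, where fewer genes were called in all. The chromosome as a whole did not shift. Its median log2 fold change minus that of the other chromosomes was -0.018 (camera, p = 0.158, adjusted p = 0.988 over 16 chromosomes, and adjusted p = 0.921 with an estimated correlation). The sign turned without a low-count filter (0.00139), with a stricter filter, on the log2(TPM + 1) scale, without wild-type replicate 1 and without tDNA-less replicate 2 (0.0286, the largest), and the test passed in none of these.

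YCL021W-A (83620 to 83997), a short reading frame, had 281 and 519 counts in the wild-type libraries and 1 and 0 in the tDNA-less libraries. Its level in the tDNA-less strain was 0.166% of that in wild type, with a 95% interval from 0.0042% to 0.928% that covers counting error alone. The reading frames YCL019W (85102 to 90415) and YCL020W (85102 to 86418) of a Ty element fell 4.59-fold and 4.56-fold. They share 98.2% and 100% of their 31-base words with other reading frames, so their counts are uncertain. All 3 lie between the tRNA gene sites YNCC0001C (82462 to 82533) and SUP53 (90859 to 90972), and LEU2 begins 352 bp beyond SUP53. The counts do not tell lower expression from sequence that the tDNA-less strain lacks. These 3 are among the 7 calls on chromosome III, and YCL020W lies within YCL019W. Fisher's exact test counts them as separate genes, so the enrichment rests in large part on a single interval. It was not tested without that interval.

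SAT4 (128470 to 130281), 681 bp from the tRNA gene YNCC0005W (127716 to 127789), fell 3.05-fold, from 76.72 ± 0.483 to 25.06 ± 2.04 CPM (edgeR, adjusted p = 2.43e-05). CIT2 (120946 to 122328), 1249 bp from SUF2 (123577 to 123648), rose 2.66-fold (edgeR, adjusted p = 0.000915). TVS1 (225563 to 227458), 484 bp from SUP61 (227942 to 228042), rose 1.94-fold, from 21.12 ± 0.631 to 40.9 ± 0.64 CPM (edgeR, adjusted p = 0.00132). YCR064C, which has no position here, rose 3.52-fold (edgeR, adjusted p = 0.014). TVS1 lost the call without tDNA-less replicate 1 and on the log2(TPM + 1) scale (highest adjusted p 0.0792), and YCR064C lost it without wild-type replicate 1 and when either tDNA-less library was left out (highest adjusted p 0.231).

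**Figure D3:**
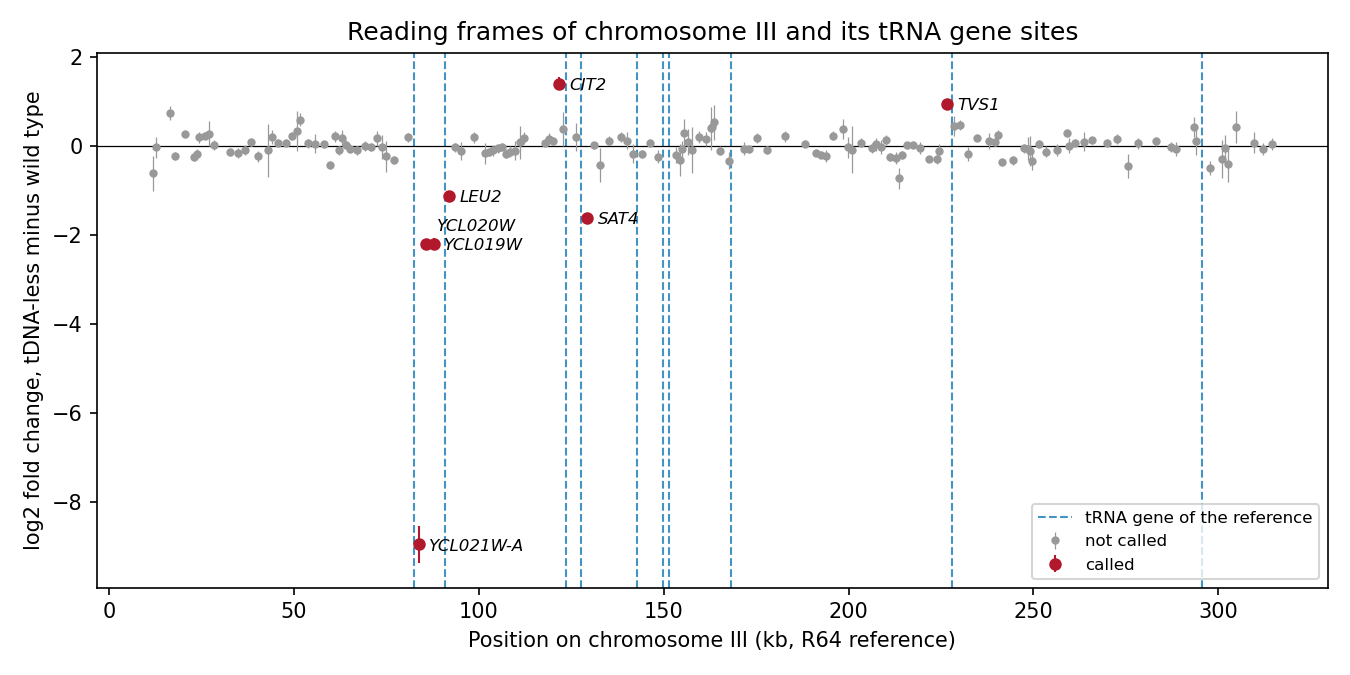
Log2 fold change (tDNA-less minus wild type, with its SE) of reading frames along chromosome III, in kb of the R64 reference, with dashed lines at the 10 tRNA genes of the annotation. Red points are called, with CIT2, SAT4 and TVS1 at 1.41, -1.61 and 0.96, grey points are not, and the fitted value of YCL021W-A depends on the prior count.

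Genes beside the chromosome III tRNA gene sites had a larger median absolute log2 fold change than the rest of the chromosome. With LEU2 and the other markers left out, the 10 genes within 1 kb had a median absolute log2 fold change of 0.355, against 0.129 for the 142 others, a difference of 0.226 (95% interval 0.046 to 0.869, one-sided permutation test on expression-matched lists, p = 0.0067). Of the 10, YCL019W and SAT4 fell, TVS1 rose and 7 did not pass, among them KCC4, BUD31 and RHB1 with log2 fold changes of 0.20, 0.46 and -0.33. The median of 0.355 lies between the sizes of change of RHB1 (SE 0.19) and YCR006C (0.38 ± 0.38), which did not pass. YCR006C had 22 and 67 counts in wild type and 38 and 45 in the tDNA-less libraries. Within 2 kb, 5 of 21 genes were called against 1 of the 131 others. The permutation p there was 1e-04, the smallest that the draws can give. These calls are not all independent, since YCL019W and YCL021W-A lie in the same interval between tRNA gene sites. YCL020W, the call among the others, overlaps YCL019W. CIT2, also within 2 kb, rose along with ACO1, IDH1 and IDH2, which lie on other chromosomes. Within 5 kb, 6 of 41 were called against 0 of 111. The difference did not pass without wild-type replicate 1 (0.0659, permutation p = 0.227) or without tDNA-less replicate 1 (0.113, permutation p = 0.128). Without wild-type replicate 2 it was 0.401.

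On the other chromosomes, whose tRNA genes are intact, the 378 genes within 1 kb of a tRNA gene had a median absolute log2 fold change of 0.136, against 0.117 for 5205 others. The difference was 0.019 (95% interval 0.002 to 0.035, one-sided permutation p = 0.0106), and without Ty reading frames it was 0.011 (permutation p = 0.174). Of these 378 genes, 12 were called, 3.17%, against 30% near the chromosome III sites, an odds ratio of 12.8 (95% interval 1.91 to 65.6, two-sided Fisher's exact test, p = 0.00479).

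At the silent mating-type loci and beside them, no gene passed over all genes tested, and CHA1 beside HML passed in some alternatives. Of 18 reading frames in this list, 13 had enough counts, and 0 were called by edgeR, DESeq2, limma-voom or limma on log2(TPM + 1), while 4 had an unadjusted p under 0.05. Adjusted over the list alone, 1 passed. It was CHA1 (15798 to 16880), a serine and threonine deaminase gene beside HML, at 10.04 ± 0.55 CPM in wild type and 16.94 ± 0.778 in the tDNA-less strain (log2 fold change 0.75 ± 0.16, edgeR adjusted p = 0.0635 over all genes and 0.0138 adjusted over the list alone). Over all genes, CHA1 was called without Ty reading frames, an alternative chosen after seeing the data (edgeR, adjusted p = 0.0474), and with an offset for GC content (0.0186). GIT1 (297049 to 298605), a glycerophosphoinositol transporter gene 1493 bp from the tRNA gene YNCC0014W (295484 to 295556) beside HMR, had a log2 fold change of -0.48 ± 0.16 (edgeR, adjusted p = 0.24, and 0.0794 adjusted over the list alone). VAC17 and MRC1 beside HML stood at -0.22 and 0.27, and CDC50 and OCA4 beside HMR at -0.01 and -0.06. Smaller counts stood behind YCL068C (-0.61 ± 0.40), YCR099C (-0.29 ± 0.42) and EMA35 (-0.03 ± 0.28).

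HMRA1 had 136 and 153 counts in wild type and 139 and 102 in the tDNA-less libraries, a log2 fold change of 0.11 ± 0.32. HMRA2 stood at 0.43 ± 0.23. The alpha2 copies at HML and MAT, HMLALPHA2 and MATALPHA2, have identical sequences and counts and stood at -0.03 ± 0.24. HMRA2 and both alpha2 copies share 100% of their sequence words with other reading frames, between which shared reads are divided. The alpha2 counts may therefore include reads of other loci. HMLALPHA1 and MATALPHA1 had 0 counts in both wild-type libraries and 2 and 1 in the tDNA-less libraries. The cells are MATa per the labels while the reference carries MATalpha. Reads of the expressed a genes at MAT are therefore counted under HMR, or under other reading frames that share their sequence. Silencing at HMR could not be read from HMRA1 or HMRA2, nor silencing at HML from the alpha2 copies. GEX1 and VBA3 beside HML had 0 counts in every library, and YCR095W-A beside HMR had 8, 2, 8 and 8.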

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

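Leaving out the Ty reading frames was chosen after the result was seen. The count of called genes, 93, was 52 with limma on log2(TPM + 1) and 211 with an offset for GC content, and ranged from 21 to 91 over the refits that left out 1 library, in which the lone library of a strain is assumed to vary like the other strain. It was 91 and 90 without wild-type replicates 1 and 2, but 21 and 30 without tDNA-less replicates 1 and 2, and the cause was not tested. The count at 2-fold or more ranged from 17 to 34 there. With the replicate number as a block, 282 genes were called, 159 higher and 123 lower, and 1 gene at the silent loci, CHA1. The labels do not say that equal numbers share a batch, so the block was not used. With 2 pairs, the correlation of the differences between replicates 1 and 2 was 0.24. This leaves open a component shared by libraries of equal number. The LEU2 change ranged from -1.26 to -0.958 without 1 library, and was not called without tDNA-less replicate 2 (-1.05, adjusted p = 0.0556). The near-site difference on chromosome III ranged from 0.0659 to 0.401 without 1 library, and that on other chromosomes from 0.017 to 0.0352. The latter was 0.0124 on log2(TPM + 1) (permutation p = 0.0839) and 0.0107 when the fit was repeated without Ty reading frames (permutation p = 0.148). The value of 0.011 in the results (permutation p = 0.174) kept the main fit and dropped the Ty reading frames afterwards. In the repeated fit 1 gene at the silent loci, CHA1, was called. The median shift of chromosome III, -0.018, was 0.00139 without a low-count filter, 0.00279 with the stricter filter and 0.00273 on log2(TPM + 1), and ranged from -0.0168 to 0.0286 without 1 library, passing the test in none of these. Lists called numbered 0 with an estimated correlation and 0 with fry. No alternative for the odds on chromosome III left out both the Ty reading frames and YCL021W-A. The odds on chromosome III passed in all 14 alternatives (2.76 to 13.6, the highest without tDNA-less replicate 1) and the HIS3 change in all 13 (5.12 to 5.66). Among single genes, 39 of 53 named lost a call in at least 1 setting and 0 reversed.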

Other observations

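Apart from those that the naming rule takes, the genes in this and the next 2 paragraphs were chosen after the result was seen. So were the test of the leucine marker and the fits without some reading frames. The comparison of genes near tRNA genes and the gene lists were chosen before, while the explanations weighed for them were picked after the fold changes of single genes had been seen. HAP4, the regulatory subunit of the activator of respiratory genes, rose 1.37-fold (edgeR's quasi-likelihood test, adjusted p = 0.0194), and ROX1, a repressor of hypoxic genes, rose 1.41-fold (edgeR, adjusted p = 0.0193), while the rise of ADR1 by 2.07-fold lost its call on the log2(TPM + 1) scale, without wild-type replicate 2 and when either tDNA-less library was left out (highest adjusted p 0.387). CAT8, another activator of gluconeogenic genes, did not pass (log2 fold change 0.08 ± 0.28). INH1, the inhibitor of the mitochondrial ATPase, rose 1.59-fold and GPD1, a glycerol-3-phosphate dehydrogenase, 1.42-fold. Among genes of iron-sulfur clusters, ISU2 and DRE2 fell 2.29-fold and 1.43-fold, while ISU1, the paralog of ISU2, stood at 0.13 ± 0.09. The zinc transporter gene ZRT1 fell 1.47-fold. At chromosome ends, COS8 rose 1.8-fold, YLL066C 1.45-fold and YML133C 1.37-fold, and YLL067C fell 1.99-fold. The list of the COS family did not pass camera, with 1 of 11 genes called (median 0.076, camera adjusted p = 0.3945). It passed fry's mixed test (adjusted p = 0.0359). HAP4, INH1, GPD1, ZRT1, COS8, YLL066C, YML133C and YLL067C lost the call when any of the 4 libraries was left out (highest adjusted p from 0.291 for YLL067C to 0.574 for YLL066C), ROX1 and DRE2 when any but wild-type replicate 2 was (0.453 and 0.406), and all of these on the log2(TPM + 1) scale. ISU2 lost it without tDNA-less replicate 1 (0.121). YLL066C, YML133C and YLL067C share 100%, 99.24% and 98.97% of their 31-base words with other reading frames.

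Ty reading frames gave some of the largest changes. YHR214C-B rose 13.3-fold, from 145.5 ± 17.5 to 1932 ± 29.3 CPM. YDR098C-A had 0 counts in both wild-type libraries against a mean of 13.68 ± 4.14 CPM in the tDNA-less strain. YDR316W-A and YGR161C-C have identical counts, and wild type held 11 counts in replicate 1 and 353 in replicate 2 against 1333 and 2163 in the tDNA-less libraries, so the wild-type libraries differ widely there. YMR051C and YER159C-A, also identical to each other, rose 3.53-fold. Their wild-type libraries differed widely too, with 103 and 432 counts against 593 and 733 in the tDNA-less libraries. Neither pair passed in DESeq2 or when either tDNA-less library was left out (highest adjusted p 0.297 and 0.2). YHR214C-B shares 99.42% of its 31-base words with other reading frames, and the others of this paragraph share 100%, so their counts are uncertain. Together, Ty reading frames held 4.22% and 3.43% of the counts in wild-type replicates 1 and 2. In tDNA-less replicates 1 and 2 the shares were 3.81% and 4.02%. The positions of Ty elements in this strain were not analysed here.

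Beside HIS3 on chromosome XV, MRM1 rose 2.16-fold, from 43.67 ± 0.0495 to 94.48 ± 3.5 CPM, and YOR203W had 7 and 2 counts in wild type against 171 and 290 in the tDNA-less libraries. DED1 and GEP3, slightly farther along the chromosome, stood at 0.10 ± 0.08 and 0.03 ± 0.10. The extent of the HIS3 insertion is not given in the sources used here. The counts do not tell reads of these loci from reads of inserted sequence.

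Of 13 leucine and branched-chain genes 7 were called lower, with a list median of -0.56 and an adjusted p of 0.435 with an estimated correlation. The arginine and lysine genes had a median of -0.155, above that of the branched-chain list (two-sided permutation test of genes between the lists, p = 0.00202). This argues against an equal fall of all amino acid genes, but the test treats genes as independent. Estimated correlations between genes were 0.549 in the arginine and lysine list and 0.144 in the branched-chain list. The sulfur genes had a median of -0.518, so a fall shared by the sulfur and branched-chain lists stays open. Without the 4 most abundant reading frames the branched-chain list had an adjusted p of 3.1e-48 (camera). Leaving them out kept 92 of the 93 calls, so this decides nothing about their share of the counts. A candidate explanation is the LEU2 marker, because leu2 mutants accumulate isopropylmalate, which activates the regulator of LEU1, OAC1 and BAT1. Both tDNA-less libraries carry the marker and the deletions together, so the effects of the marker and of the deletions on these 13 genes cannot be told apart.

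Genes near chromosome III tRNA gene sites had a larger median absolute log2 fold change than the rest of the chromosome. The difference remained without Ty reading frames (one-sided permutation p = 0.0193), an alternative chosen after the data were seen. This argues against shared reads of Ty copies in the main fit, but a permutation of genes carries no spread between libraries. Leaving out YCL021W-A as well (one-sided permutation p = 0.0181), also chosen after the data were seen, decides nothing. That reading frame lies 1087 bp from a tRNA gene, so it is a comparison gene, and dropping it could not weaken the difference. A greater spread of genes beside any tRNA gene is argued against by the other chromosomes, where the upper bound of the difference was 0.035. The share of called genes differed between the annotated chromosome III sites and the intact sites elsewhere (two-sided Fisher's exact test, p = 0.00479, and p = 0.0118 without Ty reading frames). Without Ty reading frames 2 of 9 genes near the chromosome III sites, SAT4 and TVS1, were called, against 5 of 337 elsewhere. The odds ratio was 18.4, with a wide confidence interval of 1.51 to 140. TVS1 lost its call without tDNA-less replicate 1 and on the log2(TPM + 1) scale. The other called gene, YCL019W, is a Ty reading frame whose sequence the tDNA-less strain may lack. The difference in share argues against strain-wide effects of the markers, but only weakly, since it rests on these few calls. Loss of the tRNA genes may contribute, but the LEU2 cassette replaced a pair of these genes and which ones, like the place of the HIS3 cassette, is not given in the sources used here, so a local effect of a cassette was not tested. The pattern did not pass without wild-type replicate 1 (0.0659) or tDNA-less replicate 1 (0.113).

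YSH1, ATG7, LTO1 and MSK1 held between 30.63% and 45.09% of the counts. Their sum, 4.94 M to 6.05 M, varied less than the total of the other reading frames, 7.11 M to 13.71 M, and the ratio of YSH1 to MSK1 lay between 2.57 and 2.77. Homopolymer reads are argued against, since 0 of the 4 hold a run of at least 20 identical bases. Reads of ribosomal RNA or other non-coding RNA are argued against for an exact match, since 0 of the 4 share a 31-base word with an annotated non-coding gene. What these counts come from stays open, and no biological explanation was tested.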
